A study of Polistes metricus with 16 samples.

How the data were processed

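Messenger RNA was sequenced from the heads of 16 single female larvae of the paper wasp Polistes metricus, all in the fifth and last larval instar. The labels place 4 larvae in each of 4 groups. Worker-reared larvae, destined to become queens, were taken from field nests in Iowa in late summer of 2010, and foundress-reared larvae, destined to become workers, came from the same field site in late spring of 2010. The other 8 larvae came from nests of a North Carolina population kept in a laboratory in 2009, with insect prey offered every 3 days (restricted) or every 1 day (ad libitum). Frozen heads were extracted with RNeasy columns and made into libraries with the Illumina TruSeq kit, per the labels' protocols. Replicate numbers within a group follow the order of the records and name a larva without pairing it with any other. Each larva has a sample code of its own, and the labels do not say whether parts of the code stand for a nest. Whether any larvae of one group were nest mates was therefore left open, and p-values measure the spread between these larvae.

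The deposited table holds whole-number counts for 74517 assembled transcripts in 16 columns, one per larva. Bowtie2 and eXpress are named in the submitters' processing notes, with no version. The version and source of the transcript assembly beyond the identifiers, the handling of read strand and the filters before counting are not given in the sources used here. eXpress can write either all fragments compatible with a transcript or an estimate that divides shared fragments, and which of these the deposited counts are is not stated. If the former, a fragment shared by near-identical transcripts was counted for each, so that isoforms and paralogs of one gene can repeat the same change. No 2 rows with at least 100 counts were identical. Levels less their group mean were correlated above 0.9 in 7.1% of 15837 pairs of consecutively numbered identifiers, taken among the 20000 most abundant transcripts. The share was 0.126% in random pairs, but these were drawn from all tested transcripts, so the 2 sets are unlike in abundance. Counts of transcripts are therefore not taken as counts of genes. The table pairs no identifier with a gene name, and no reference was used here. The 22 gene lists fixed for larval tissue, nutrient signalling, hormones, storage proteins and cell type markers were therefore not run, and transcripts are reported by identifier. No marker of muscle, silk gland, nervous tissue or haemocytes could be read.

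Totals ran from 28359372 to 37626473 counts per library. In total 870 transcripts had 0 counts in every library. Transcripts with too few counts were removed with edgeR's filterByExpr by group, which left 36337 transcripts (48.8%) holding 99.74% of the counts. The main test was edgeR 4.0.16 in R 4.3.3, with TMM scaling factors, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment, and a transcript was called at an adjusted p under 0.05. One model with a mean for each of the 4 groups was fitted to all 16 libraries, which gives 12 residual degrees of freedom. From it came the caste contrast (worker-reared over foundress-reared), the nutrition contrast (ad libitum over restricted) and the interaction contrast (the caste log2 fold change minus the nutrition log2 fold change). The contrast of the 8 field libraries with the 8 laboratory libraries, and the sum of the caste and nutrition contrasts, were added after seeing the data. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM (counts scaled to TMM-adjusted library totals), as mean ± SD of 4 libraries.

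Sets of transcripts taken from one pair of groups were tested for direction in the 8 libraries of the other pair with fry on voom values (limma 3.58.1), and the mean level of each set was compared by a two-sided exact permutation test. The 200 transcripts with the smallest p in each direction were chosen in a fit of the first 8 libraries alone, and the sets of called transcripts in the fit of all 16, which share an estimate of spread. fry tests whether a set moves on balance in one direction, and does not compare it with other transcripts. It used the members of a set that passed the filter in the 8 libraries tested. The exact test used those that passed it over all 16, so the 2 tests can differ in members. Numbers of set members are those of fry unless stated. Library measures were compared with two-sided exact permutation tests over 70 assignments of 8 libraries, whose smallest possible p is 0.0286. Principal components were taken from log2 CPM (prior count 2) of the 500 most variable transcripts. Pairwise chi-square statistics per degree of freedom ran from 65.2 to 924 in the 24 pairs of libraries within a group and from 51.4 to 876 in the 96 pairs between groups, so in no pair did the counts agree within sampling noise.

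Sets of 400 transcripts (the 200 with the smallest p in each direction, ranked without a given larva) were used to ask whether that larva lay nearer to the mean of its own group or of the other group of its pair. Distances between levels and the mean levels of sets were taken on log2 of CPM plus 0.05. This placement was added after seeing the data.

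Before the data were examined the following rule was set for the transcripts named: without gene names, the 2 higher and the 2 lower transcripts with the smallest adjusted p and non-overlapping CPM in each contrast. No transcript passed the nutrition test, so those with the smallest p are given there as not passing. For the interaction non-overlap was not required, and its transcripts were chosen by the smallest adjusted p alone. The alternatives set at the same time were RLE and upper quartile scaling, no low-count filter, a stricter filter (CPM above 1 in all 4 libraries of a group), DESeq2 1.42.0, limma voom, a fit on only the 8 libraries compared, an adjusted p under 0.1 and the omission of each library in turn. Covariates estimated with sva 3.50.0, thinning of all libraries to 28359372 counts and the joint omission of restricted replicate 4 and ad libitum replicate 3 were added after seeing the data.

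The fit was tested on simulated counts with the depths of these libraries. Each transcript was drawn independently with its fitted spread, and only transcripts with a mean CPM above 1 were changed. Variation shared between transcripts within a group was not simulated, so recovery and false calls in the real larvae can differ. Of 100 transcripts changed 2-fold in the caste contrast 22% were recovered, and of 100 changed 4-fold 70%, with 5 false calls among 97 over 35429 transcripts tested. In the simulated nutrition contrast, over the same number of transcripts, 13% of the 2-fold and 72% of the 4-fold changes were recovered, with 2 false calls among 87.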

Results

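Gene expression in the heads of fifth-instar female larvae of Polistes metricus was measured by RNA sequencing of single larvae. Paper wasp colonies are started in spring by foundresses, whose early daughters become workers, and the workers later rear the next generation of queens. Caste is set during larval life and is thought to depend on feeding. The design therefore placed a caste contrast from field nests (4 worker-reared, queen-destined larvae and 4 foundress-reared, worker-destined larvae) beside a nutrition contrast from laboratory nests (4 larvae on restricted protein and 4 fed ad libitum). Season differed together with rearing caste, and field and laboratory larvae differed in year, place and origin.

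Library totals ran from 30084017 to 37626473 counts in the 4 worker-reared larvae, from 28359372 to 32569316 in foundress-reared larvae, from 29487724 to 33561419 in restricted larvae and from 29048017 to 33471057 in ad libitum larvae. At least 1 count was found for 58758 ± 1326 transcripts in worker-reared, 54891 ± 2086 in foundress-reared, 58968 ± 2057 in restricted and 57942 ± 1207 in ad libitum larvae (SD, n = 4 each). The 10 most abundant transcripts of each library held 9.3% ± 1.22 of counts in worker-reared larvae and 18.1% ± 9.69 in foundress-reared larvae, where they ranged from 10% to 32.1%. The corresponding shares were 12.9% ± 4.63 in restricted and 15.2% ± 8.89 in ad libitum larvae. Of 8 exact permutation tests of library measures between the groups of a pair, the smallest p was 0.0571 (transcripts detected, worker-reared against foundress-reared), and each adjusted p over the 8 tests was 0.343 or above.

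Larvae of one group differed widely. The first principal component held 45.7% of the variance of the 500 most variable transcripts, and 12.2% of its variance lay between the 4 groups (permutation test, p = 0.644). Its standard deviation was 43.4 among worker-reared, 41.2 among foundress-reared, 45.6 among restricted and 37.2 among ad libitum larvae. Restricted replicate 4 lay at -55.9, apart from the other restricted larvae at 24.8 to 40.8. The third component, with 12.5% of the variance, had 73% of its variance between groups (permutation test, p = 0.00089). The most abundant transcript took from 0.0407% to 11.3% of a library's counts, a 278-fold range.

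**Figure D1:**
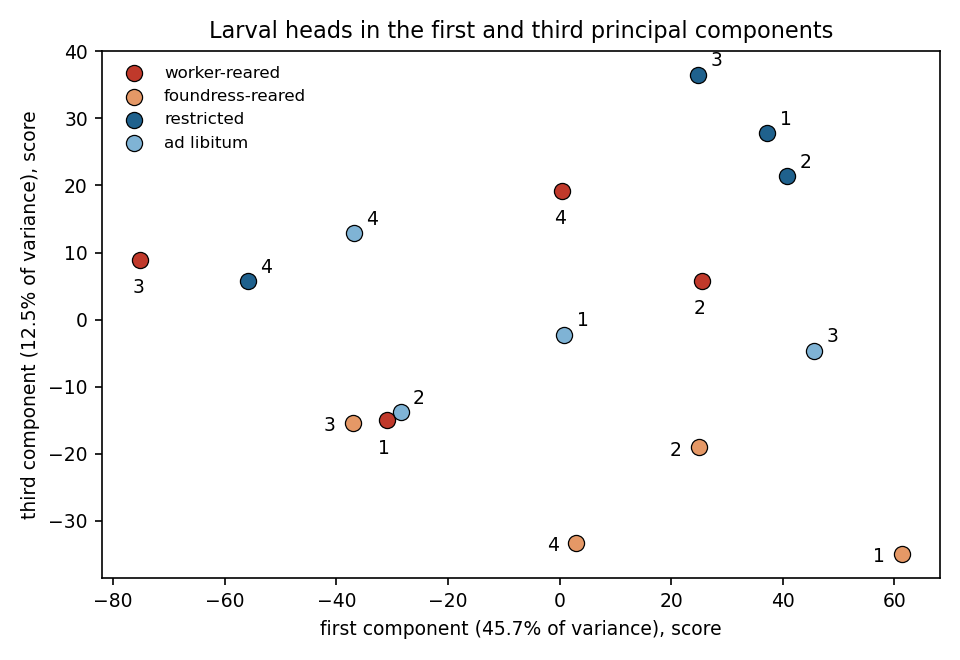
Scores of the 16 larval heads on the first (45.7% of variance) and the third (12.5%) principal components of log2 CPM, 1 point per larva, coloured by group and numbered by replicate. Each group spreads along the first component. On the third the foundress-reared larvae (-34.9 to -15.4) lie below all larvae of the other 3 groups, but narrowly, as worker-reared replicate 1 lies at -15.

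The caste contrast asked which transcripts differ between larvae on the queen and the worker path. In worker-reared larvae 9 transcripts were higher and 7 lower than in foundress-reared larvae, with a median fitted difference of 2.87-fold (1.68-fold to 96.7-fold). PmetTSAr1.1-022057 rose from 0.632 ± 0.145 CPM in foundress-reared to 3.7 ± 1.12 CPM in worker-reared larvae (log2 fold change 2.56, SE 0.327, edgeR adjusted p = 0.0139), and lay between these levels in restricted (1.24 ± 0.328 CPM) and ad libitum larvae (1.48 ± 0.522 CPM). PmetTSAr1.1-021577 rose 1.98-fold, from 16.4 ± 1.07 to 32.5 ± 4.91 CPM (log2 fold change 0.98, SE 0.145, edgeR adjusted p = 0.0449). PmetTSAr1.1-013766 was highest in foundress-reared larvae, at 8.52 ± 3.21 CPM against 1.09 ± 0.304 CPM in worker-reared larvae (log2 fold change -2.95, SE 0.329, edgeR adjusted p = 0.0077). Its level was 0.959 ± 0.241 CPM in restricted and 0.83 ± 0.324 CPM in ad libitum larvae. PmetTSAr1.1-004133 was 2.39-fold lower in worker-reared larvae, at 22 ± 3.88 against 52.6 ± 3.34 CPM (log2 fold change -1.26, SE 0.15, edgeR adjusted p = 0.0087), while restricted larvae had 34.2 ± 6.37 CPM and ad libitum larvae 44.6 ± 4.25 CPM. All 16 called transcripts had CPM that did not overlap between the 2 groups. The files do not pair these identifiers with gene names.

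An unadjusted p under 0.05 was reached by 5838 of the 36337 transcripts, against 1817 expected by chance, and an adjusted p under 0.1 by 197. The count of 16 was 0 when only the 8 field libraries were fitted, 979 with DESeq2 and 4 with limma voom, and fell to 1 without foundress-reared replicate 2. The call of PmetTSAr1.1-021577 was lost in 8 of 20 alternative settings, and those of the other named transcripts in 1 or 2. These 20 did not include the omission of laboratory libraries, which share the fit. Such omissions kept from 3 (without ad libitum replicate 2) to 16 (without ad libitum replicate 3) of the 16 calls. CPM did not overlap between the 2 groups for 3419 transcripts (chance gives 2.86%, or 1038), but 3 of the 35 ways to split the 8 field libraries, the labelled one included, gave as many.

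**Figure D2:**
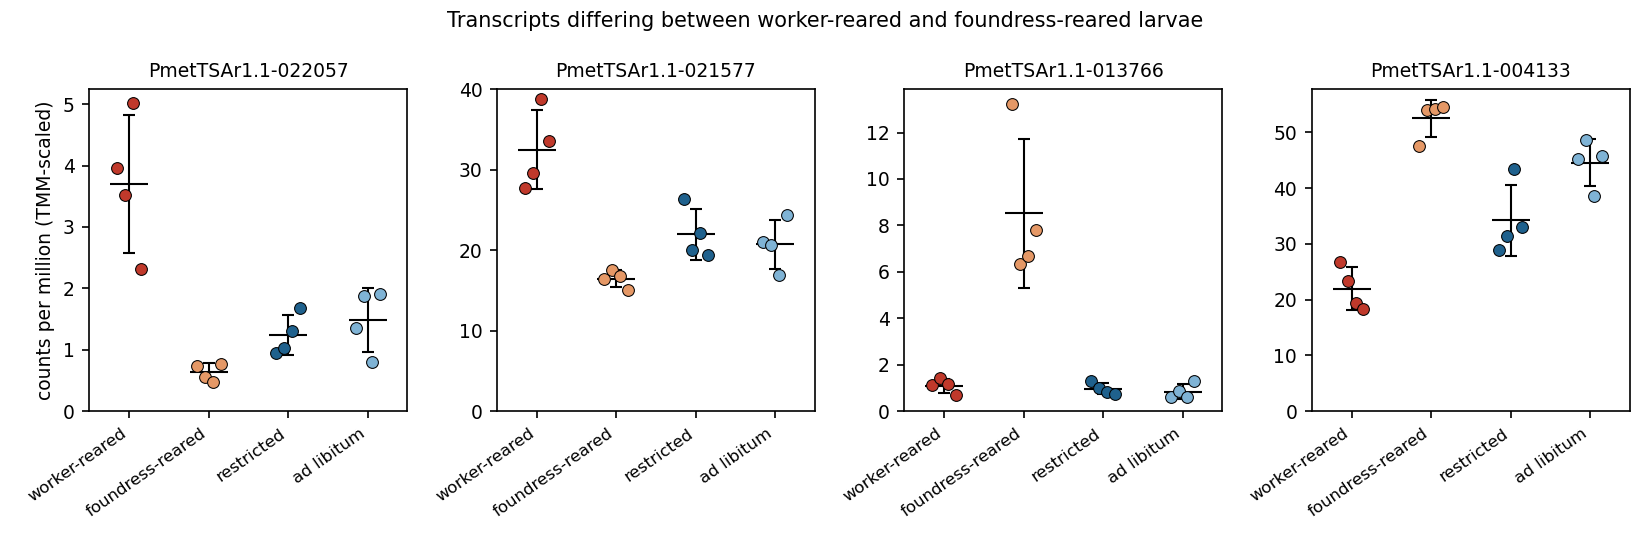
Levels in TMM-scaled CPM of the 4 transcripts named for the caste contrast, 1 point per larva, with the mean (long bar) and SD (error bar) of 4 larvae per group. The first 2 transcripts were higher in each worker-reared larva than in any foundress-reared larva, and the last 2 were lower.

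The nutrition contrast asked which transcripts respond to the supply of protein. No transcript was called between ad libitum and restricted larvae with edgeR, limma voom called 0 and DESeq2 484, and 4949 transcripts had an unadjusted p under 0.05. The smallest adjusted p, 0.178, was shared by 173 transcripts. Those named here were chosen for CPM that did not overlap between the groups, which 128 of the 173 had. PmetTSAr1.1-008414 measured 1.87 ± 0.211 CPM in ad libitum and 0.794 ± 0.172 CPM in restricted larvae (log2 fold change 1.22, SE 0.223, edgeR adjusted p = 0.178). PmetTSAr1.1-012473 measured 14.1 ± 2.3 against 7.42 ± 1.4 CPM (log2 fold change 0.92, SE 0.175). In the other direction, PmetTSAr1.1-040445 measured 0.284 ± 0.0602 CPM in ad libitum and 1.55 ± 0.611 CPM in restricted larvae (log2 fold change -2.42, SE 0.357). PmetTSAr1.1-009276 measured 3.54 ± 0.678 against 8.34 ± 2.06 CPM (log2 fold change -1.23, SE 0.202).

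The nutrition count rested on 1 larva. Without restricted replicate 4, the remaining 3 restricted larvae differed from the 4 ad libitum larvae in 3016 transcripts (1656 higher and 1360 lower with ad libitum). Omission of any other laboratory library gave 0. When the 400 transcripts that best separated the remaining 3 restricted from the 4 ad libitum larvae were read in restricted replicate 4, 7 of them (1.75%) lay nearer to the restricted mean. For the other 7 laboratory larvae the same measure, each time ranked without that larva, placed 64.8% to 89% of transcripts with their own group.

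**Figure D3:**
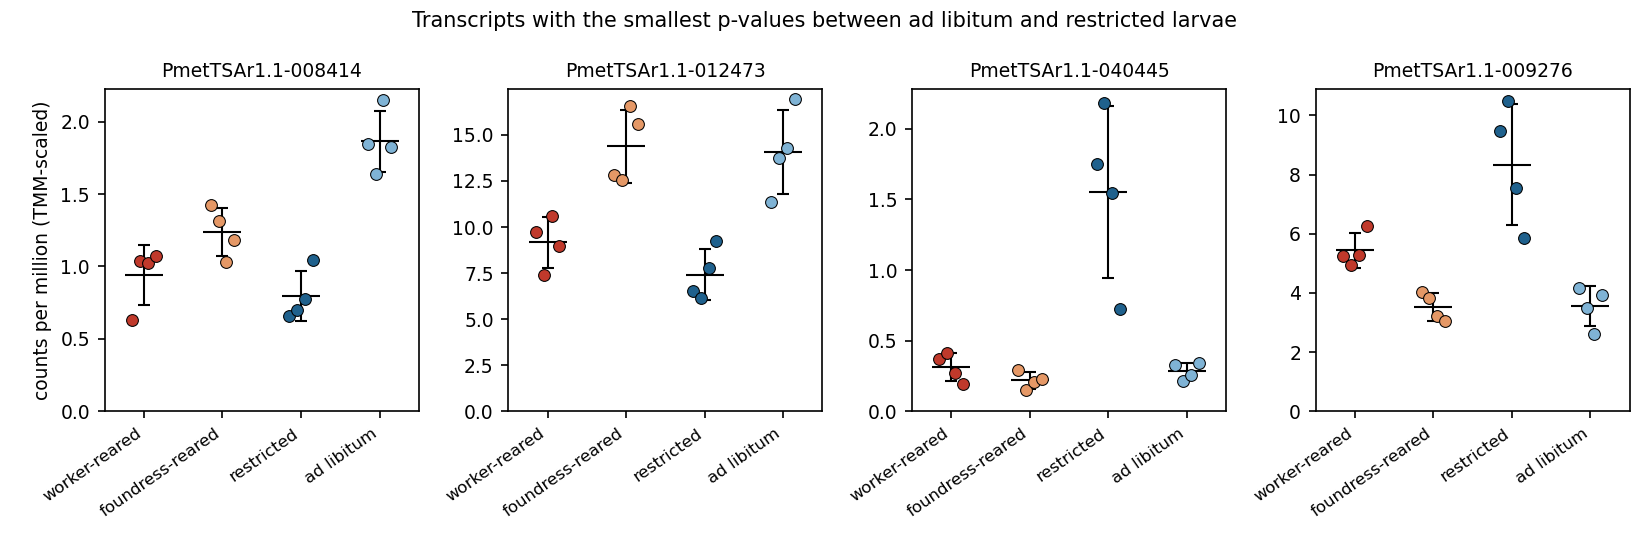
Levels in TMM-scaled CPM of the 4 transcripts named for the nutrition contrast, 1 point per larva, with the mean (long bar) and SD (error bar) of 4 larvae per group. Ad libitum and restricted larvae do not overlap in any panel, as the rule for naming required, and the adjusted p was 0.178 in each.

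The interaction contrast asked whether the caste and nutrition differences were alike. They differed for 199 transcripts, 102 with the larger value in the caste contrast and 97 with the larger value in the nutrition contrast, and in 197 of the 199 the fitted fold changes had opposite signs. A test of the difference favours transcripts with opposite signs, so much of that number follows from the selection. Of the 199, 171 had an unadjusted p under 0.05 in both contrasts, and the median absolute log2 fold change was 1.02 for caste and 0.92 for nutrition. PmetTSAr1.1-007756 measured 7.68 ± 2.57 CPM in worker-reared and 9.98 ± 2.73 CPM in restricted larvae, against 2.51 ± 0.511 CPM in foundress-reared and 3.61 ± 0.194 CPM in ad libitum larvae (interaction log2 fold change 3.07, SE 0.358, edgeR adjusted p = 0.0107). PmetTSAr1.1-009293 followed the same order of groups, at 4.19 ± 1.34 and 7.65 ± 1.84 CPM against 1.5 ± 0.459 and 2.8 ± 0.351 CPM (2.92, SE 0.374). PmetTSAr1.1-004133, named for caste above, had an interaction log2 fold change of -1.64 (SE 0.21, edgeR adjusted p = 0.0107). PmetTSAr1.1-020810 measured 13.7 ± 1.65 CPM in worker-reared and 16.4 ± 1.82 CPM in restricted larvae, against 23.4 ± 2.4 CPM in foundress-reared and 22.1 ± 1.83 CPM in ad libitum larvae (-1.19, SE 0.177, edgeR adjusted p = 0.0298).

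No transcript was called in both the caste and the nutrition contrast with edgeR, and DESeq2 called 46 in both, 44 of them in opposite directions. At an unadjusted p under 0.05 in both, there were 1031 transcripts, of which 938 (91%) had opposite signs. Transcripts higher in worker-reared larvae and lower with ad libitum food numbered 436 (205 expected from independent lists), and those lower in worker-reared larvae and higher with ad libitum food 502 (189 expected). Same-sign transcripts numbered 42 (162 expected) and 51 (239 expected). Across all transcripts, which are not independent replicates, the correlation of the caste and nutrition fold changes was -0.14 (Spearman -0.0973). The 199 calls fell to 0 without ad libitum replicate 2 and rose to 3117 without restricted replicate 4, and the correlation became 0.0826 without ad libitum replicate 3. With upper quartile scaling 254 transcripts differed, 70.9% of them larger in the caste contrast, against 51.3% with TMM. The call of PmetTSAr1.1-020810 was lost in 9 of 27 alternative settings, and those of the other named transcripts in 1 to 3.

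**Figure D4:**
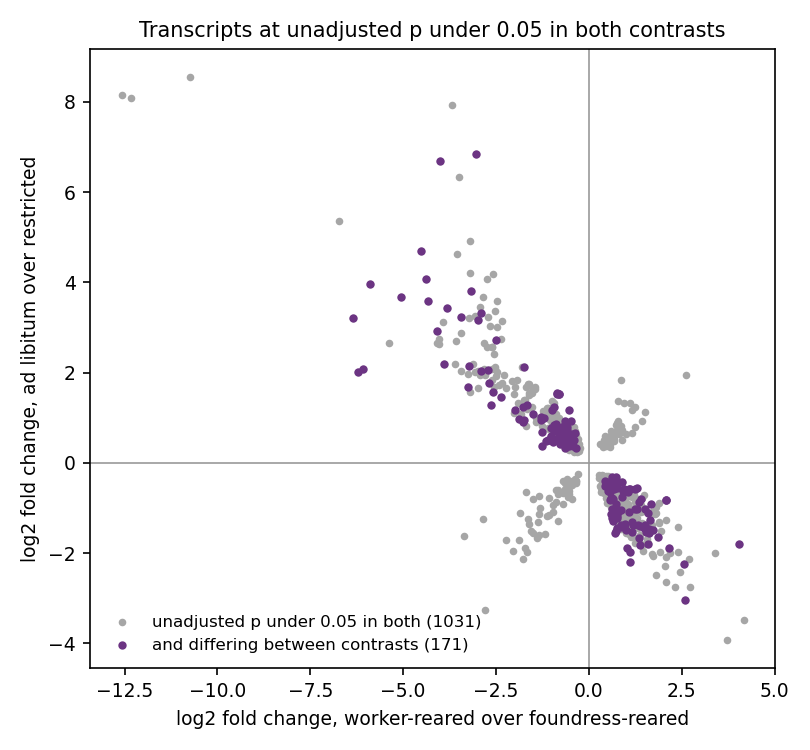
Fitted log2 fold changes of the 1031 transcripts with an unadjusted p under 0.05 in both contrasts, worker-reared over foundress-reared on the horizontal axis and ad libitum over restricted on the vertical axis, 1 point per transcript, with those whose interaction was called in purple. In total 938 points lie in the 2 quadrants of opposite sign.

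Sets of transcripts chosen in one pair of groups were then tested in the larvae of the other pair. The 191 measured transcripts most strongly higher with ad libitum food were lower in worker-reared than in foundress-reared larvae, with 33 of 191 higher and a median log2 fold change of -0.418 (limma fry, adjusted p = 0.00353 over 6 sets). An exact permutation test of the set's mean level gave p = 0.0286, the smallest that 8 libraries allow, and an adjusted p = 0.0856. Of the 182 most strongly lower with ad libitum food, 119 were higher in worker-reared larvae (median 0.205), which passed neither test (limma fry, adjusted p = 0.288; exact permutation p = 0.114). Conversely, of the 5 measured transcripts called lower in worker-reared larvae, 4 had a positive sign with ad libitum food (median log2 fold change 0.373, limma fry, adjusted p = 0.0262). The exact permutation test took all 7 called lower, 5 of them with a positive sign in the fit of all 16 libraries (p = 0.0571). Of the longer list of 189, 161 had a positive sign (median 0.341, limma fry, adjusted p = 0.0844, exact permutation p = 0.0286, adjusted p = 0.0856). Of the 9 called higher in worker-reared larvae, 1 was higher with ad libitum food (median -0.122; limma fry, adjusted p = 0.0844; exact permutation p = 0.0571), as were 59 of the longer list of 189 (median -0.157; limma fry, adjusted p = 0.304; exact permutation p = 0.371). After adjustment over the 6 sets, each exact permutation p was 0.0856 or above.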

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

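The tests of opposite signs at an unadjusted p under 0.05, with surrogate variables, of the place of single larvae and of splits without restricted replicate 4 were chosen only after the results they follow up were seen. Of 88 groups of 4 values examined, 7 held a value far from the other 3, where chance gives about 4.4. Transcript PmetTSAr1.1-004133 measured 47.6 CPM in foundress-reared replicate 1 against 54.1 to 54.5 CPM in the rest of its group, and PmetTSAr1.1-008414 measured 0.63 CPM in worker-reared replicate 1 against 1.02 to 1.07 CPM. Ad libitum replicate 3 had 2.28 CPM of PmetTSAr1.1-009293 against 2.94 to 3.04 CPM. Restricted replicate 1 had 0.986 CPM of PmetTSAr1.1-014183 against 0.317 to 0.407 CPM, and foundress-reared replicate 2 had 7.06 CPM of PmetTSAr1.1-006826 against 3.28 to 3.73 CPM. Restricted replicate 4 had counts for 62026 transcripts against 57586 to 58253 in the other restricted larvae, and a first component score of -55.9 against 24.8 to 40.8.

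Restricted replicate 4 is the larva without which the nutrition count goes from 0 to 3016. The first component correlated at 0.999 with itself after removal of the 100 most abundant transcripts and at 1.00 after thinning to equal totals. Its place there thus did not rest on the counts of those transcripts or on unequal totals. A link to library composition is not excluded. The component followed the share of the top 10 transcripts over 16 larvae (Spearman 0.831, permutation p = 0.00012). That share was 7.58% in restricted replicate 4, against 11.5% to 18.7% in the other restricted larvae. An exchange with ad libitum replicate 3 gave 1418 transcripts with non-overlapping CPM against 661 under the labels as given, among 9582 transcripts not tied to the component in the field larvae, which was what an exchange required. It also required that ad libitum replicate 3 be out of place, whereas 78% of 400 such transcripts, ranked without either larva, placed it with its own group, which argues against an exchange, and the same 400 placed restricted replicate 4 with its group in 4%. A wrong label of restricted replicate 4 alone stays open, as 1.75% of the transcripts ranked without it placed it with the restricted larvae, and so does a larva of a restricted nest that was in the state of a well-fed one, which no label tests.

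In 199 transcripts the caste and nutrition fold changes differed by the interaction test, although the caste contrast called 16 and the nutrition contrast 0. The interaction log2 fold changes of the named transcripts were 3.07 for PmetTSAr1.1-007756, 2.92 for PmetTSAr1.1-009293, -1.64 for PmetTSAr1.1-004133 and -1.19 for PmetTSAr1.1-020810. Thinning to equal totals left 150 calls, which argues against depth. The greater precision of a contrast over 16 libraries was another candidate. In each named transcript the interaction had a larger standard error than either contrast, which argues against it for these transcripts. For PmetTSAr1.1-007756 it was 0.358, against 0.255 for caste and 0.252 for nutrition. The equally precise sum of both contrasts called 0 (3541 at an unadjusted p under 0.05), but effects of opposite sign cancel in a sum and add in the interaction, so that count decides nothing. A further candidate explanation is that worker-reared larvae share part of the expression state of restricted larvae. Transcripts chosen in the laboratory larvae moved in the field larvae against their nutrition sign in one set (limma fry, adjusted p = 0.00353). The exact permutation test of that set did not pass after adjustment (adjusted p = 0.0856). The fry p of the other set was 0.24, where under 0.05 had been asked of both. A p above the threshold with 119 of 182 transcripts in that direction does not exclude this explanation. Season and rearing caste cannot be told apart in these libraries.

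Chance was examined by splitting the labels anew. For the caste contrast 1 of 35 splits, the labelled one, gave any call (16, highest other 0). That argues against chance for that count, but it is the smallest share that 35 splits allow. The count also fell to 0 in the fit of the 8 field libraries alone, so chance is not firmly excluded. For the nutrition contrast the labelled count was 0, which all 35 splits must reach, so the comparison says nothing about that count. Of the other splits 1 gave any call (6530), and it joined ad libitum replicate 3 to restricted replicates 1 to 3 and restricted replicate 4 to the other ad libitum larvae. That split followed the first component, on which the side of restricted replicates 1 to 3 scored 24.8 to 45.6 and the other side -55.9 to 0.812. A wrong label of restricted replicate 4 was not separated from this structure of the samples. Without restricted replicate 4, 1 of 35 splits of the 7 libraries gave as many as 3016 calls, and the highest other, 2673, again moved ad libitum replicate 3 to the restricted side. For the interaction 3 of 100 drawn splits gave 199 or more, with a highest other count of 10889. That share is under 0.05, but 10889 is many times the labelled count and came from the same exchanged laboratory split, with foundress-reared replicate 3 in the place of worker-reared replicate 2. This split too followed the first component. Its worker-reared side held the lowest field scores (-75.1 to 0.507, others 2.9 to 61.3). Its restricted side held the lowest laboratory scores (-55.9 to 0.812, others 24.8 to 45.6). A split with 3911 calls held the same laboratory exchange, with foundress-reared replicate 2 in the place of worker-reared replicate 2. Other groupings thus gave far larger counts, and the share does not settle chance for the 199. For opposite signs at an unadjusted p under 0.05, 2 of 100 splits gave 938 or more (highest other 4738). That number was put to the splits only after the opposite signs had been seen, so its small share does not exclude chance. Chance is also not excluded for their share of 91%, which 7 of 100 splits reached (highest other 98.7%), while 10 of 100 had as large a share of same signs. The correlation of -0.14 was reached in size by 48 of 100 splits (highest other 0.615), so chance is not excluded for it. Nor is it excluded for the larger counts of other tools. DESeq2's 979 caste calls were reached by 2 of 35 splits (highest other 1585) and its 484 nutrition calls by 3 of 35 (highest other 8947). With 2 surrogate variables the 399 caste calls were reached by 2 of 35 splits (highest other 838) and the 27 nutrition calls by 2 of 35 (highest other 434).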

How the results depend on the processing

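Thinning, surrogate variables, the joint omission of restricted replicate 4 and ad libitum replicate 3, the omission of libraries from the set tests, and all settings of the field against laboratory contrast were chosen after seeing the data. The causes of the shifts below were not tested, except that fits with fewer libraries have fewer degrees of freedom. The caste count of 16 was 39 with the stricter filter, 979 with DESeq2, 4 with limma voom, 0 with the 8 field libraries alone, 84 without both doubted libraries, 6 after thinning, 419 and 399 with 1 and 2 surrogate variables and 197 at an adjusted p under 0.1. Omission of 1 field library gave 1 (foundress-reared replicate 2) to 46 (foundress-reared replicate 3), with 9, 3, 4 and 8 without worker-reared replicates 1 to 4 and 4 without foundress-reared replicate 4, and omission of 1 laboratory library gave 3 to 33. The nutrition count of 0 was 484 with DESeq2, 4527 without both doubted libraries, 27 and 4 with 2 and 3 surrogate variables, and 0 to 3016 on omission of 1 library, the latter without restricted replicate 4. The interaction count of 199 was 44 with no filter, 567 with the stricter filter, 2172 with DESeq2, 17 with limma voom, 3254 without both doubted libraries, 3435, 3600 and 16 with 1, 2 and 3 surrogate variables and 1800 at an adjusted p under 0.1. Omission of 1 library gave 0 (ad libitum replicate 2) to 3117 (restricted replicate 4), with 27, 8, 9 and 5 without worker-reared replicates 1 to 4, 295, 2, 309 and 13 without foundress-reared replicates 1 to 4, 6, 4 and 70 without restricted replicates 1 to 3, and 5, 7 and 25 without ad libitum replicates 1, 3 and 4. Transcripts called in both contrasts numbered 46 with DESeq2, 12 without both doubted libraries, 6 and 2 with 2 and 3 surrogate variables and 0 to 6 on omission of 1 library (6 without restricted replicate 4). The fold change correlation of -0.14 was 0.114 without both doubted libraries, -0.594 over the transcripts called in either contrast, -0.408, -0.382 and -0.35 with 1, 2 and 3 surrogate variables, and -0.335 to 0.0826 on omission of 1 library, the latter without ad libitum replicate 3, and -0.141 to -0.0894 in other settings. The field against laboratory count of 356 was 1155 with DESeq2, 1753 without both doubted libraries, 1019 and 636 with 1 and 2 surrogate variables, 755 at an adjusted p under 0.1 and 193 (restricted replicate 2) to 2277 (restricted replicate 4) on omission of 1 library, with 208 without worker-reared replicate 4, 211 and 212 without foundress-reared replicates 2 and 4, 215 without restricted replicate 1, and 201, 222 and 223 without ad libitum replicates 1, 2 and 4. The fry p of the set lower with ad libitum food was 0.0426 to 0.387 on omission of 1 field library, passing without worker-reared replicate 3. That of the transcripts called higher in worker-reared larvae was 0.047 (without restricted replicate 4) to 0.126, and that of those called lower was 0.0563 with the longer list, which itself gave 0.0443 without restricted replicate 4, 0.0463 without ad libitum replicate 4 and up to 0.146 on other omissions. Other settings kept the counts within 1.5 times and the set tests on their side of the threshold. For the transcripts named for caste or nutrition, only libraries of that pair were omitted in turn. None of the 16 named contrasts reversed in the settings counted, and 333 of their values stayed on the same side of the threshold, 28 lost the call and 14 gained it. RLE and upper quartile scaling moved the median log2 fold change of each contrast by under 0.1. In the simulation, which left out variation shared between transcripts, 22% of 2-fold caste changes were recovered. Most differences of that size could therefore go undetected with these depths, group sizes and spreads. The lists of named genes and markers were not run. No paired analysis was possible because the replicate numbers do not pair larvae.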

Other observations

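The field against laboratory contrast was added after seeing the data, as was its test of neighbouring transcripts. Across both seasons and both diets, 106 transcripts were higher and 250 lower in the 8 field larvae than in the 8 laboratory larvae. The excess of lower transcripts was lost without restricted replicate 4 (1195 higher and 1082 lower), without both it and ad libitum replicate 3 (901 and 852) and with 3 surrogate variables (254 and 229), and it was narrower with DESeq2 (482 and 673) and with 1 or 2 surrogate variables (470 and 549, 261 and 375). PmetTSAr1.1-014184 measured 7.44 ± 1.38 CPM in worker-reared and 6.97 ± 4.5 CPM in foundress-reared larvae against 0.193 ± 0.0833 CPM in restricted and 0.188 ± 0.0981 CPM in ad libitum larvae, a 37-fold difference (log2 fold change 5.21, SE 0.347, edgeR adjusted p = 4.09e-06). PmetTSAr1.1-014183, the next identifier, was 24-fold higher in the field (log2 fold change 4.58, SE 0.375, edgeR adjusted p = 2.43e-05). PmetTSAr1.1-006807 was 14.2-fold lower in the field, at 2.58 ± 0.329 and 1.75 ± 1.1 CPM against 31.7 ± 4.86 CPM in restricted and 28.7 ± 2.28 CPM in ad libitum larvae (log2 fold change -3.82, SE 0.261, edgeR adjusted p = 4.09e-06). PmetTSAr1.1-006826 was 6.7-fold lower (log2 fold change -2.74, SE 0.19, edgeR adjusted p = 4.09e-06). All 4 were called in each of 27 alternative settings. CPM did not overlap between field and laboratory for 175 of all transcripts tested, where chance gives 6, and 152 of the 175 were among the 356 called.

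Of 100 random assignments of the 16 libraries, 1, the labelled one, gave as many as 356 calls (highest other 3). That argues against chance for the count, though it is the smallest share that 100 draws allow. The draws treat larvae as independent, and nest mates within a group are left open. A trade of reads between near-identical transcripts would give neighbours called in opposite directions. Of called transcripts 1.12% had such a neighbour (4 of 356, where random sets averaged 2.39). A neighbour called in the same direction was found for 68 (random sets averaged 3.2). After thinning to equal totals 341 were called, which argues against depth. Year, state, nest population and rearing place differ together here, so population variants that alter how reads match the assembly, diet and housing cannot be told apart. A hypothesis that a few loci account for part of the list, in line with the 68 neighbours, was not tested further because identifiers are not placed on a genome.

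The spread between larvae of one group was widest at both ends of the range of abundance. The median within-group SD was 0.544 on the log2 scale for the 100 most abundant transcripts, 0.314 for the next 900, 0.27 for those ranked 1001 to 10000 and 0.503 for the remaining 26337. The first component correlated with the share of the top 10 transcripts over 16 larvae (r = 0.524, permutation p = 0.0332, adjusted over 3 measures 0.0498; Spearman 0.831, permutation p = 0.00012; r = 0.8 without the 2 larvae farthest from the median), with r = 0.33 among field and 0.776 among laboratory larvae. It also correlated with transcripts detected (r = -0.546, permutation p = 0.0274, adjusted 0.0498; Spearman -0.512, permutation p = 0.0456; r = -0.517 without the 2 farthest), with r = -0.526 in the field and -0.825 in the laboratory. For the library total r was 0.0024 (permutation p = 0.993; Spearman 0, permutation p = 1).

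Levels of the caste transcripts in the laboratory groups were mixed. Of the 16 called, restricted larvae lay nearer to worker-reared larvae in 9 and ad libitum larvae in 5, and 13 had opposite signs in the caste and nutrition contrasts, while 15 were also called in the interaction. In the field, the transcripts ranked without a larva placed foundress-reared replicates 1 and 3 with their own group in 48.2% and 42.2% of 400 transcripts, and the other 6 field larvae in 62.2% to 87.5%.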
